A study of Mus musculus with 6 samples.

How the data were processed

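Small RNA was sequenced from mouse pancreas with pancreatitis, in 3 libraries from mice with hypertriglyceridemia (a raised level of triglycerides in the blood) and 3 libraries from control mice without it. Per the labels' protocols, RNA was extracted with Trizol and the libraries were made with the NEXTflex Small RNA-Seq Kit v3, which adds adapters to both ends of small RNAs before amplification. Bowtie version 1.1.1, a short-read aligner, and the mouse genome build GRCm38 are named in the submitters' processing notes. Adapter trimming, the release of the miRNA annotation, the mismatches allowed and the treatment of reads matching several miRNAs are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

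The deposited table held 1077 mature miRNAs with whole-number read counts per library, per the file headers and from the values. Beside each column of counts, the authors gave a TPM value (counts scaled to library size, with no length term), per the file headers. In each of the 4657 cells with a count above 0, the TPM equalled the count divided by 1 total per library and scaled by the same constant, to within 0.1% or 0.02 TPM. That total lay between 1.70% and 1.95% below the sum of the library's counts. Reads of miRNAs with the same sequence were counted for each of them. Among miRNAs with a total of at least 30 counts, 24 in 11 sets had identical counts in all 6 libraries, and the repeats held 0.245% of all counts. The counts of miR-101a-3p and miR-101c differed by 0.0466% to 0.0924%. Values of such miRNAs, including miR-199a-3p with miR-199b-3p, miR-486a with miR-486b and members of the Sfmbt2 cluster, cannot be assigned to 1 of them.

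The total counts per library ranged from 6514498 to 19773579. A count of 0 allows a level of up to 0.152 to 0.461 CPM (counts scaled to library size), taking 3 counts as the limit; this covers counting error only, since reads amplified by PCR are not independent molecules. Counts were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, trimmed mean of M-values (TMM) scaling, and the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The levels below are CPM divided by the TMM factor of the library. Fold changes are log2 values of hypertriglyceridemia over control with their standard errors (SE), and intervals are 95% confidence intervals. DESeq2 1.42.0, limma-voom and limma 3.58.1 on log2(TPM + 1) were run as alternatives.

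The test was first run on simulated counts with the means, depths and dispersion of these 488 miRNAs and 6 libraries, in 20 data sets. With 200 miRNAs changed, it recovered 14% of those changed by 1.5-fold, 43.9% of 2-fold, 87.6% of 4-fold and 94.3% of 8-fold changes, and 2.95% of its calls were false. With 20 miRNAs changed, it recovered 0% of 1.5-fold, 9% of 2-fold, 79% of 4-fold and 84% of 8-fold changes, and 10.4% of its calls were false. Each miRNA was drawn independently, without variation shared by many miRNAs of a library, so these rates may not hold for the real libraries.

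Before the data were examined, 19 miRNA lists were fixed: markers of acinar, islet endocrine, ductal epithelial, leukocyte, erythroid, endothelial, stellate and mesenchymal, striated muscle and liver cells; miRNAs known from injury and inflammation and from lipid metabolism; the let-7, miR-17-92, miR-29, miR-30, miR-181 and miR-34 families; and the Dlk1-Dio3 and Sfmbt2 clusters. Lists share members, for example miR-223 of the leukocyte and the injury list. The 18 lists with at least 3 tested members were compared by camera of limma with a preset correlation of 0.01, which compares the members with all other miRNAs, and adjusted over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. Fry tests the members against no change and not against the other miRNAs. With an estimated correlation, camera also uses the residual degrees of freedom, 4 with all 6 libraries. A call lost there may thus come from fewer degrees of freedom as well as from the correlation. With the estimated correlation many lists share the adjusted camera p of 0.733, which is the unadjusted p of the let-7 list, so this value does not separate them. On simulated independent members, the stellate and mesenchymal list was called in 100% of 20 data sets with a shift of -0.5 and in 0% with none. That shift was larger than the median of -0.18 observed for this list. Real members may vary together, so these rates may not hold for the real lists. The miRNAs named in the text were set by a rule fixed at the same time. It takes up to 12 miRNAs past the threshold in each direction whose groups did not overlap, or the 5 of smallest p where fewer than 5 passed. It adds the 10 most abundant miRNAs, up to 4 members of each list past the threshold, and the 4 most abundant tested members of each list. It gave 75 miRNAs; others are said to have been chosen after their values were seen.

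The labels give both groups replicate numbers 1 to 3 without saying what the numbers share. Deviations of log2 CPM from the group means correlated between libraries of the same number with r = 0.466 for number 1, 0.187 for number 2 and 0.253 for number 3. By the limit of 0.1 set for every pair, the numbers were taken to pair the libraries, a pairing that rests on the values alone. Control 3 with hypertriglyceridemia 2 (0.226) and control 2 with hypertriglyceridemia 3 (0.215) correlated about as well as the pairs numbered 2 and 3. Deviations cancel out over the libraries of a group, so the correlation of the libraries numbered 1 can by itself make the others correlate. The limit therefore hardly tests the pairs numbered 2 and 3. Results without the replicate block are the main ones, and the blocked value is given where it moved a call. Counts of libraries of 1 group differed by more than counting noise (chi-square per degree of freedom 121.7 to 1721), so no library was given more than once; repeat preparations of 1 sample can differ by that much and are not excluded.

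The alternatives were other scalings (DESeq2 size factors, upper quartile, library size), no or a stricter count filter, the other tests, the replicate block, a fold minimum, removal of the 5 most abundant miRNAs, and leaving out each library in turn. After the data were seen, fits without both libraries numbered 1, with library weights, with a lymphocyte covariate, with identical miRNAs kept once, and on TPM were added. The annotation of hairpin genes came from GENCODE M21, which uses the build GRCm38. Figures were drawn with matplotlib under Python. All 6 libraries and both kinds of column were used.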

Results

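MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were counted in inflamed mouse pancreas to compare pancreatitis with and without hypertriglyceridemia. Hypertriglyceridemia is a recognised cause of acute pancreatitis. There were 3 control libraries and 3 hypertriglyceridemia libraries. The control libraries held 8994031, 8920079 and 19773579 counts, and the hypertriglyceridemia libraries 6514498, 18384606 and 10279395. Between 728 and 835 mature miRNAs were detected per library, 773 ± 32.6 in control and 779 ± 53.6 in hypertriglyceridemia (SD, n = 3 each).

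In both groups the most abundant miRNA was miR-148a-3p, which is enriched in acinar cells, the enzyme-secreting bulk of the pancreas. It alone took 36.6% ± 4.83 of all counts in control and 40.6% ± 4.50 in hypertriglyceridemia pancreas (SD, n = 3 each; exact two-sided permutation p = 0.4). It was followed by miR-21a-5p, an injury-induced miRNA, at 117390 ± 23912 and 106060 ± 13447 CPM, and by miR-375-3p, abundant in islets, at 37346 ± 3343 and 38762 ± 5792 CPM. The 10 most abundant miRNAs together held 69.4% ± 2.70 of the control and 70.1% ± 2.27 of the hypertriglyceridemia counts, a difference of 0.660 percentage points (exact permutation p = 0.6). The number of detected miRNAs (exact permutation p = 1) and the total count (exact permutation p = 0.7) differed by less than the spread between replicates as well. With 3 against 3 libraries the smallest p of this test is 0.1.

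No miRNA passed the threshold between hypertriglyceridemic and control pancreatitis: of 488 tested miRNAs, edgeR called 0 higher and 0 lower, and the smallest adjusted p was 0.996. At an unadjusted p under 0.05 there were 12 miRNAs, 7 higher and 5 lower, where 24.4 are expected with no effect. The values of the 2 groups did not overlap for 39 miRNAs, or 7.99%, and chance gives 10%. DESeq2 called 0 (18 unadjusted), limma-voom 0 (17 unadjusted) and limma on TPM 0 (12 unadjusted). With the replicate block the unadjusted count was 27, and the adjusted count 0. Leaving out control 1 gave 2 adjusted calls and 37 unadjusted, leaving out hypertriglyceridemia 1 gave 45 unadjusted, and leaving out both libraries numbered 1, a choice made after seeing the data, gave 4 adjusted and 70 unadjusted calls. The median SE of a log2 fold change was 0.29.

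The 5 miRNAs with the smallest p among the higher, none of which passed (adjusted p = 0.996 in edgeR for each), included 1 abundant species. This was miR-7a-5p, a miRNA of endocrine cells, at 2971 ± 1217 CPM in control and 5244 ± 367 CPM in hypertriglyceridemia (SD, n = 3 each), a log2 fold change of 0.82 ± 0.27 (SE). Control 1, at 4374 CPM, stood near the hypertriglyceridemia libraries, and controls 2 and 3 lay at 2348 and 2191 CPM. The other 4 were rare: miR-666-5p of the Dlk1-Dio3 cluster (0.717 and 1.98 CPM; log2 1.44 ± 0.36), miR-129-1-3p (5.53 and 10.2 CPM; 0.88 ± 0.28), miR-3065-3p (0.748 and 2.44 CPM; 1.62 ± 0.51) and miR-196b-5p, encoded in the Hoxa cluster (1.06 and 9.07 CPM; 3.13 ± 1.097). For miR-196b-5p the groups overlapped, with 15.4, 0.555 and 11.3 CPM in the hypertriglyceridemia libraries.

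Among the lower ones (adjusted p = 0.996 in edgeR for each), miR-125b-5p, abundant in mesenchymal cells, stood at 2534 ± 542 CPM in control and 1758 ± 159 CPM in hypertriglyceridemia (SD, n = 3 each), a log2 fold change of -0.53 ± 0.19 (SE). The muscle miRNA miR-133b-3p was at 1.72 and 0.510 CPM (log2 -1.75 ± 0.45), and miR-503-3p at 2.43 and 1.05 CPM (-1.19 ± 0.36). For miR-9-3p the levels were 24.6 and 15.4 CPM (-0.68 ± 0.25). The groups overlapped for miR-135a-5p, at 24.4 and 10.1 CPM (-1.26 ± 0.51), of which control 2 alone held 40.1 CPM.

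**Figure D1:**
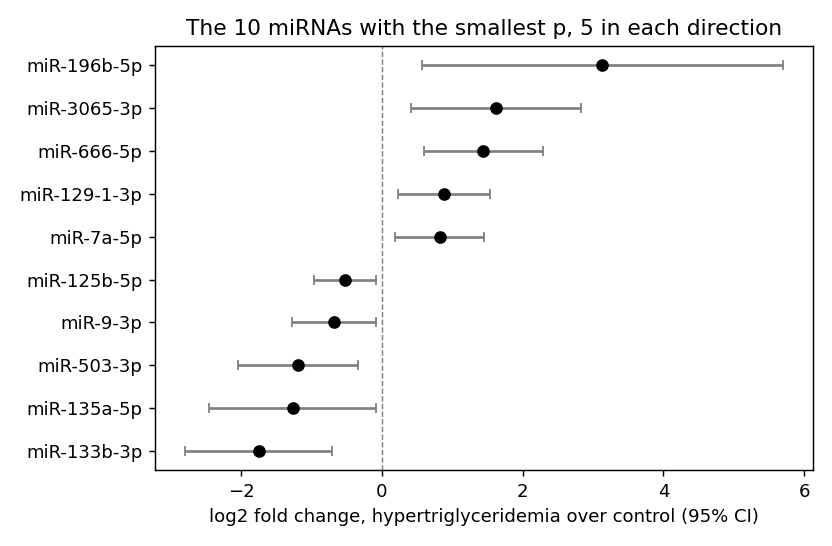
Log2 fold changes of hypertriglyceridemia over control (horizontal axis) for 10 miRNAs, the 5 with the smallest p in each direction, with 95% confidence intervals as bars. The point for miR-196b-5p, at 3.13, has the widest interval (0.57 to 5.69), and none of the 10 passed the adjusted threshold in edgeR.

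On GRCm38, with GENCODE M21 gene models, the hairpin gene Mir666 lies on chromosome 12 from 109717085 to 109717183 (+ strand), outside any longer gene on that strand. Mir129-1 lies on chromosome 6 from 29022619 to 29022691 (+) in an exon of the noncoding gene Gm3294, and Mir3065 on chromosome 11 from 120014767 to 120014853 (+), outside longer genes of its strand. The mature miR-7a-5p comes from Mir7-1, in an intron of Hnrnpk on chromosome 13 (58392779 to 58392886, - strand), and from Mir7-2, on chromosome 7 from 78888277 to 78888373 (+). Mir196b lies on chromosome 6 from 52230081 to 52230165 (-) and overlaps an exon of a transcript annotated to Hoxa9. Mir133b lies on chromosome 1 from 20682769 to 20682887 (+) in an exon of the noncoding gene Gm28653, and Mir503 on chromosome X from 53053984 to 53054054 (-). The hairpins of miR-125b-5p are Mir125b-2 on chromosome 16 (77646273 to 77646343, +), in an intron of Mir99ahg, and Mir125b-1 on chromosome 9 (41581926 to 41582002, +), in an intron of 3110039I08Rik. Those of miR-9-3p are Mir9-1 on chromosome 3 (88215598 to 88215686, +), Mir9-2 on chromosome 13 (83738814 to 83738885, +) and Mir9-3 on chromosome 7 (79505264 to 79505353, +), all within noncoding genes. Mir135a-2 lies in an intron of Rmst on chromosome 10 (92072086 to 92072185, -), and Mir135a-1 on chromosome 9 (106154124 to 106154213, +).

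The lists of pancreatic cell types gave no call for acinar, islet or duct cells. Of 8 tested acinar members, 7 were higher and 1 lower, with a median log2 fold change of 0.12 (camera adjusted p = 0.314), and none passed in edgeR. Members of this list were miR-148a-3p (0.22 ± 0.23, SE), miR-217-5p (0.13 ± 0.32), miR-216a-5p (0.20 ± 0.24) and miR-216b-5p (0.05 ± 0.26). The islet list, with 8 of 12 higher and a median of 0.05 (adjusted p = 0.257), held miR-7a-5p and, chosen after its values were seen, miR-7b-5p (0.85 ± 0.32), beside miR-375-3p (0.05 ± 0.16), miR-182-5p (0.04 ± 0.27) and miR-183-5p (-0.06 ± 0.23). Of the duct list of epithelial miRNAs, 8 of 15 were higher (median 0.02, adjusted p = 0.545), among them miR-200a-3p (0.20 ± 0.20) and miR-200b-3p (-0.01 ± 0.19). Over each of the 3 lists alone, edgeR called 0 members, and its smallest p adjusted over the list alone was 0.191, for the islet list. In the camera fit that left out both libraries numbered 1, the acinar, islet and duct lists were called higher at the preset correlation (adjusted p = 0.00687, 0.0320 and 0.0464), as they were without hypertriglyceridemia 1 alone (0.000284, 0.0149 and 0.00887) and, for the acinar list, without control 3 (0.0331). With an estimated correlation the fit without both libraries numbered 1 called 0 lists, and its smallest adjusted p was 0.503.

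MiRNAs of stellate and mesenchymal cells, the fibre-forming cells of the pancreas, lay lower as a group in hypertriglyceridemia: 19 of 20 members were lower, with a median log2 fold change of -0.18 (camera adjusted p = 0.00811, preset correlation). The call did not hold with an estimated correlation (adjusted p = 0.723), without control 1 (adjusted p = 0.0583) or without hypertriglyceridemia 2 (adjusted p = 0.132). None of the 20 passed alone in edgeR, nor over the list alone. Besides miR-125b-5p, the values were -0.45 ± 0.52 for miR-143-3p, -0.30 ± 0.17 for miR-10a-5p and -0.07 ± 0.14 for miR-99a-5p (SE). The sign turned by more than the SE for miR-143-3p without control 1 (0.38) and for miR-99a-5p without both libraries numbered 1 (0.12). The smooth-muscle miRNA miR-143-3p was highest in the library numbered 1 of both groups. It stood at 56171 CPM in control 1 against 22365 and 12982 in controls 2 and 3, and at 32184 CPM in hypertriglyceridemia 1 against 16158 and 18513 in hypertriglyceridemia 2 and 3.

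The striated muscle miRNAs had fitted log2 fold changes below 0 in 4 of 4 tested members, with a median of -0.75 (camera adjusted p = 0.0425, preset correlation). The list was not called with an estimated correlation (adjusted p = 0.733), nor without control 1 (0.385), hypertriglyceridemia 1 (0.189), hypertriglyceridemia 2 (0.132) or both libraries numbered 1 (0.411). Its members were miR-133b-3p, miR-133a-3p (-0.94 ± 0.42, SE), miR-1a-3p (-0.56 ± 0.43) and miR-206-3p (-0.03 ± 0.63), whose group means were 1.33 and 1.35 CPM. The sign turned by more than the SE for miR-1a-3p without control 1 (0.20) or without both libraries numbered 1 (0.20), and for miR-206-3p without control 3 (0.66). Over the list alone, 1 of the 4 was called by edgeR, miR-133b-3p (adjusted p = 0.0210 in edgeR, adjusted over the list alone), and over all miRNAs 0. This miRNA was near the counting floor, at 0.516, 0.370 and 0.645 CPM in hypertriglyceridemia 1, 2 and 3. A count of 0 there allows up to 0.461, 0.163 and 0.292 CPM. In control 1, miR-1a-3p reached 544 CPM, with group means of 308 ± 206 and 209 ± 26.3 CPM (SD, n = 3 each).

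The Dlk1-Dio3 cluster, a large imprinted miRNA cluster on chromosome 12, lay higher in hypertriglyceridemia: 46 of 60 tested members were higher and 14 lower, with a median log2 fold change of 0.15 (camera adjusted p = 3.52e-06, preset correlation). The call did not hold with an estimated correlation (adjusted p = 0.733; the estimate was 0.33) or without control 3 (adjusted p = 0.0689). No member passed in edgeR, over all miRNAs or adjusted over the list alone. The most abundant members were miR-127-3p (356 ± 60.8 and 418 ± 73.7 CPM, SD, n = 3 each; log2 0.23 ± 0.20, SE), miR-379-5p (0.06 ± 0.20), miR-411-5p (-0.02 ± 0.16) and miR-541-5p (0.30 ± 0.17). The median deviation of the cluster from the mean of all libraries was 0.27 in control 1 and 0.28 in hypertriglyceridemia 1, against -0.24 and -0.27 in controls 2 and 3 and 0.044 and -0.0075 in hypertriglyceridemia 2 and 3.

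Of blood and vessel cells, the leukocyte list was not called (camera adjusted p = 0.250). Its median was 0.12 with 9 of 14 members higher, while camera put it on the lower side. At the preset correlation it was called lower without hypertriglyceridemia 1 (adjusted p = 0.000284) and without both libraries numbered 1 (6.27e-06; 0.503 with an estimated correlation). The myeloid miRNA miR-223-3p was at 1956 ± 1441 CPM in control and 903 ± 119 CPM in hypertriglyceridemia (SD, n = 3 each; log2 -1.11 ± 0.52, SE), and miR-146b-5p had a log2 fold change of -0.44 ± 0.33. The leukocyte miRNAs miR-150-5p (0.91 ± 1.503) and miR-142a-5p (0.40 ± 1.07) were set apart by the libraries numbered 1. Erythroid miRNAs, such as miR-451a (0.30 ± 0.41), miR-144-5p (0.32 ± 0.38) and miR-486a-5p or miR-486b-5p (-0.02 ± 0.38, 1 shared count), had a median of -0.02 with 3 of 7 higher. Camera placed that list on the higher side (adjusted p = 0.309; 0.0107 without control 1 and 0.0427 without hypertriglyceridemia 3), and its median turned positive with scaling by library size. With an estimated correlation over all 6 libraries its adjusted p was 0.733. Of 6 endothelial members 4 were lower (median -0.08, adjusted p = 0.501), with miR-126a-3p at 0.03 ± 0.14, miR-126a-5p at 0.04 ± 0.17, miR-92a-3p at -0.25 ± 0.17 and miR-139-5p at -0.37 ± 0.25. The liver miRNA miR-122-5p was at 5.09 ± 2.96 and 2.96 ± 3.14 CPM (log2 -0.80 ± 0.83), and as the single member of its list it had no list test.

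Of the miRNAs known from injury and inflammation, 17 of 27 were lower, with a median of -0.10 (camera adjusted p = 0.0928; 0.0451 with the replicate block). With an estimated correlation, fitted without the block, the adjusted p was 0.733. At the preset correlation the list was called lower without control 1 (adjusted p = 0.00884) and without both libraries numbered 1 (0.00662), where an estimated correlation called 0 lists. Members included miR-21a-5p (-0.15 ± 0.18, SE), miR-221-3p (-0.33 ± 0.23), miR-223-3p and the p53-induced miR-34a-5p (0.06 ± 0.29). With the block and the preset correlation the number of called lists was 4 in place of 3. The lipid metabolism list was close to evenly divided, with 17 of 32 higher and a median of 0.00 (adjusted p = 0.545), and miR-27b-3p (0.02 ± 0.16), miR-29a-3p (0.06 ± 0.14) and miR-30c-5p (-0.07 ± 0.13) had narrow errors. The 95% interval of miR-27b-3p, for example, ran from -0.36 to 0.40.

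None of the remaining families was called by camera with all 6 libraries. The let-7 family had 12 of 22 members lower (median -0.04, adjusted p = 0.501), with let-7f-5p at -0.02 ± 0.21, let-7g-5p at 0.04 ± 0.16, let-7a-5p at -0.14 ± 0.15 and let-7c-5p at -0.14 ± 0.15 (SE). The miR-17-92 paralogs had 10 of 19 higher (median 0.00, mean -0.03, camera on the lower side, adjusted p = 0.309), including miR-25-3p (0.02 ± 0.19), miR-19b-3p (0.00 ± 0.24) and miR-93-5p (0.01 ± 0.13). Of the miR-29 family, regulators of collagen, 6 of 7 were higher (median 0.16, adjusted p = 0.309), with miR-29b-3p at 0.21 ± 0.14 and miR-29c-3p at 0.18 ± 0.19. This list was called higher without control 3 (adjusted p = 0.0145) and without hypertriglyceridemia 1 (0.0297). The miR-30 family had 7 of 11 lower (median -0.07, adjusted p = 0.696), with miR-30a-5p at 0.00 ± 0.17 and miR-30d-5p at -0.08 ± 0.13. The miR-181 family had 5 of 7 lower (median -0.04, adjusted p = 0.639; miR-181a-5p -0.02 ± 0.17, miR-181c-5p 0.13 ± 0.25), and the miR-34 family 5 of 7 lower (median -0.09, adjusted p = 0.671; miR-34c-5p -0.06 ± 0.24). In the Sfmbt2 cluster, whose members share reads, 12 of 22 were higher (median 0.14), while camera placed it on the lower side (adjusted p = 0.309). It was called lower without control 3 (adjusted p = 0.0145), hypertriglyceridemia 1 (6.78e-05) or both libraries numbered 1 (0.00687). With an estimated correlation over all 6 libraries the adjusted p was 0.733 for both the miR-29 and the Sfmbt2 list. The Sfmbt2 members miR-669c-5p and miR-467e-5p had values of 0.41 ± 0.58 and -0.21 ± 0.66, and miR-466a-3p and miR-466e-3p, with 1 shared count, 0.16 ± 0.75. Medians of the duct, erythroid, lipid and miR-17-92 lists changed sign between scalings, those of the other 15 did not.

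**Figure D2:**
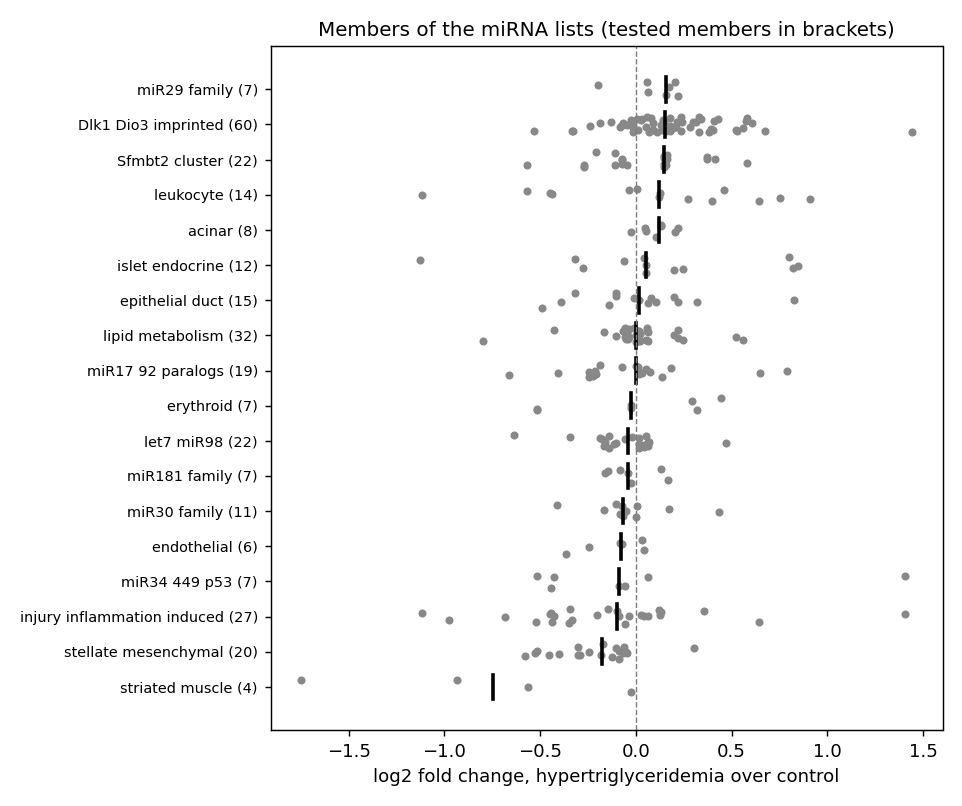
Log2 fold changes of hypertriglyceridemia over control (horizontal axis) of the tested members of 18 miRNA lists (points), with the median of each list as a black line. The 4 striated muscle members lie at or below 0 (median -0.75), 19 of 20 stellate and mesenchymal members below 0 (median -0.18), and 46 of 60 Dlk1-Dio3 members above 0 (median 0.15).

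The largest differences among the 6 libraries ran across the groups. The first principal component, with 49.3% of the variance, set control 1 (-7.66) and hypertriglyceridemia 1 (-13.3) apart from the other 4 libraries (3.29 to 6.74). At the end of this component where the libraries numbered 1 lay, the 4 leading miRNAs were, in order, miR-150-5p, miR-3964, miR-150-3p and miR-142a-5p. All but miR-3964 belong to the leukocyte list. Loadings at the other end were not ranked. In control 1, 2 and 3, miR-150-5p stood at 798, 66.2 and 103 CPM, and in the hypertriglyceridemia libraries at 1726, 46.7 and 46.2 CPM. For miR-142a-5p the levels were 1236, 473 and 221 CPM, and 2204, 170 and 169 CPM. The myeloid miR-223-3p had another order, with 663, 3510 and 1695 CPM in control and 993, 769 and 948 CPM in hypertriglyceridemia. The second component, with 19.3% of the variance, held controls 2 and 3 at 5.97 and 6.64 and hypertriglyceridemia 2 and 3 at -4.82 and -5.66, with both libraries numbered 1 between them. Pearson correlations of log2 CPM across miRNAs, which are not independent replicates, were 0.978 to 0.990 within control, 0.970 to 0.990 within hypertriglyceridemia and 0.972 to 0.987 between the groups.

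**Figure D3:**
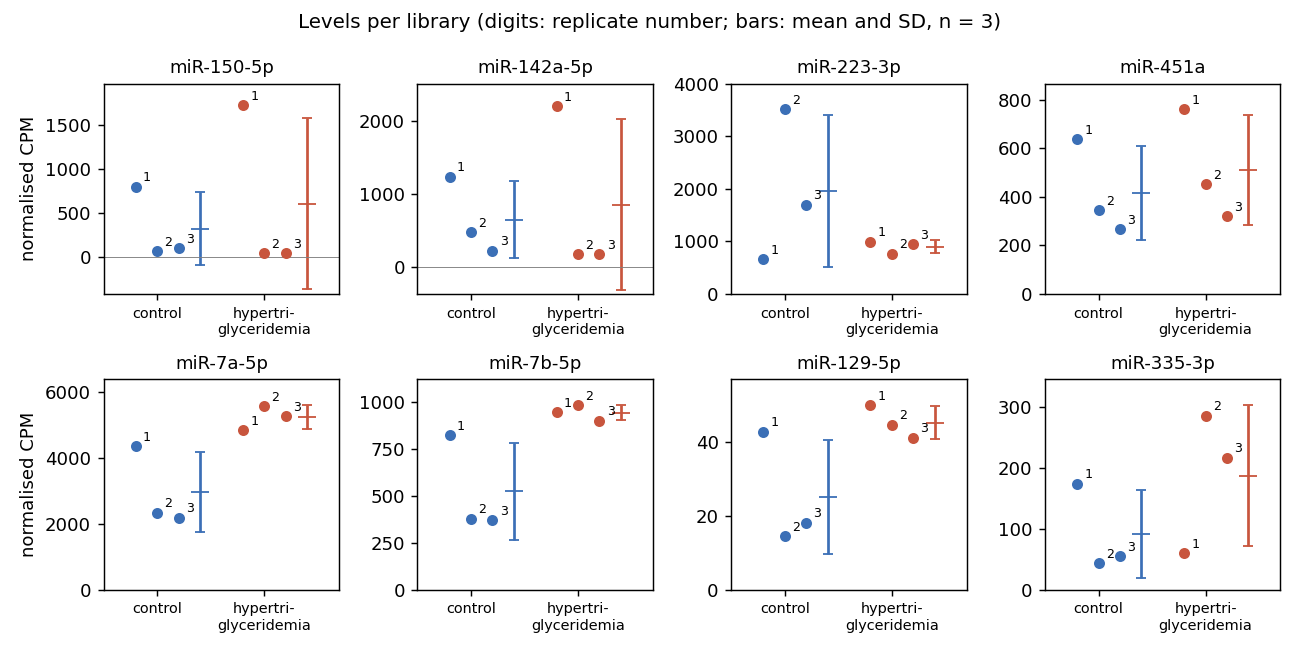
Normalised CPM (vertical axes, linear) of 8 miRNAs in the 3 control (blue) and 3 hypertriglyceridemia libraries (red), with the replicate number beside each point and the mean and SD as bars. The libraries numbered 1 hold the highest miR-150-5p values (798 and 1726 CPM), and control 1 lies above controls 2 and 3 for miR-7a-5p (4374 CPM against 2348 and 2191).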

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

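The fits on TPM, without both libraries numbered 1, with library weights, with the lymphocyte covariate and with identical miRNAs kept once were chosen after seeing the data; pseudocounts and mean filters were applied to TPM alone, and no p-values of the authors were used. The adjusted count of 0 became 1 with no count filter (miR-135b-5p, at 28.8 CPM in control 2), 4 without both libraries numbered 1, and 0 to 2 when 1 library was left out; the other settings gave 0. The unadjusted count of 12 became 32 with no filter, 7 with the stricter filter, 27 with the replicate block, 70 without both libraries numbered 1, 56 with library weights, 29 with the lymphocyte covariate, 31 on TPM with no filter, 6 on TPM with a mean of at least 10, and 9 to 45 when 1 library was left out (37 without control 1, 45 without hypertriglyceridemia 1). The stricter filters tested fewer miRNAs, and edgeR with no count filter tested all 1077 in place of 488. These counts are therefore not out of equal totals, and more are expected by chance where more are tested. Otherwise the cause was not tested. The count of called lists, 3, became 0 with an estimated correlation, 0 with fry (a test against no change, not against the other miRNAs), 8 without both libraries numbered 1 (0 with an estimated correlation), and 1 to 8 when 1 library was left out (5 without control 3, 8 without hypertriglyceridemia 1, 1 without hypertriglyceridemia 2). The replicate block added the injury list and changed no other call. The adjusted p of the stellate and mesenchymal list was 0.723 with an estimated correlation, 0.706 for the other question that fry asks, 0.664 without both libraries numbered 1 and with an estimated correlation, and 0.00229 to 0.132 when 1 library was left out. For striated muscle these were 0.733, 0.706, 0.665 and 0.00877 to 0.385, with 0.411 without both libraries numbered 1 at the preset correlation. For Dlk1-Dio3 they were 0.733, 0.742, 0.503 and 1.16e-10 to 0.0689. Of 1772 values of named miRNAs under alternatives, 262 changed sign, 27 of them by more than the SE, and only these are listed as reversed; 1 passed the adjusted threshold (miR-7a-5p without both libraries numbered 1). Without both libraries numbered 1, values reversed for miR-200b-3p (0.23), miR-142a-5p (-0.95), miR-150-5p (-0.77), miR-99a-5p (0.12), miR-1a-3p (0.20), and miR-466a-3p and miR-466e-3p (both -0.64). With library weights they reversed for miR-142a-5p (-1.21), miR-150-5p (-1.01), miR-181c-5p (-0.13), miR-669c-5p (-0.27), and miR-466a-3p and miR-466e-3p (both -0.64). Leaving out 1 library gave ranges that cross 0: -0.17 to 0.20 for let-7f-5p, -0.83 to 0.38 for miR-143-3p, -0.12 to 0.21 for miR-200b-3p, -0.23 to 0.33 for miR-182-5p, -1.90 to 1.30 for miR-142a-5p, -2.78 to 2.86 for miR-150-5p, -0.37 to 0.42 for miR-486a-5p and miR-486b-5p, -0.86 to 0.20 for miR-1a-3p, -0.41 to 0.66 for miR-206-3p, -1.04 to 0.51 for miR-467e-5p, -0.47 to 0.78 for miR-669c-5p, and -1.07 to 0.62 for miR-466a-3p and miR-466e-3p. The difference in the share of the 10 most abundant miRNAs stayed within the spread between replicates, from -0.864 to 1.93 percentage points. Depth sets the lowest level that can be seen, up to 0.461 CPM for a count of 0. The SE was 0.16 at its 10th and 0.63 at its 90th percentile over all tested miRNAs.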

Other observations

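The miRNAs in this part were chosen after their values were seen, except those named by the rule. Without both libraries numbered 1, 4 miRNAs were called higher by edgeR in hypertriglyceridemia, with 2 libraries left per group. They were miR-7a-5p (log2 1.35 ± 0.13, SE, adjusted p = 0.00441), miR-7b-5p (1.42 ± 0.14, 0.00441), miR-335-3p, from an intron of the imprinted gene Mest (2.44 ± 0.20, 0.00441), and the neuroendocrine miR-129-5p (1.48 ± 0.19, 0.0168). Of the other alternatives, leaving out control 1 called miR-129-5p (1.53 ± 0.19) and miR-7b-5p (1.39 ± 0.18), with adjusted p = 0.0371 in edgeR for both, and the rest called none of the 4. In all 6 libraries, miR-7b-5p stood at 824, 379 and 369 CPM in control and 944, 981 and 900 CPM in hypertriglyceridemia. For miR-129-5p the levels were 42.8, 14.5 and 18.1 CPM, and 49.97, 44.7 and 41.2 CPM. For miR-335-3p they were 174, 43.6 and 55.2 CPM, and 60.3, 286 and 217 CPM, so that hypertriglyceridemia 1 lay among the controls.

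Other miRNAs set apart in the libraries numbered 1 belonged to the X-linked miR-106a-363 cluster. Of its members, miR-20b-5p stood at 7.27 CPM in control 1 and 18.7 CPM in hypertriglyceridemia 1, against 1.36 to 2.70 CPM in the other 4 libraries. The levels of miR-363-3p were 4.55 and 12.1 CPM against 0.678 to 3.06 CPM. Erythroid miR-451a was 1.06 above the other controls on the log2 scale in control 1, and 0.98 above the other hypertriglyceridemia libraries in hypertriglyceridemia 1. The Sfmbt2 list had median deviations of 0.72 and 1.29 in these 2 libraries, against -0.10 to -1.11 in the other 4.

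The counts over other splits were planned before the data were examined; the remaining tests below were chosen after their results were seen. The 6 libraries divide into 3 and 3 in 10 ways, too few for a share under 0.05. For the adjusted count the splits test nothing, since all 10 must give at least the real 0; the highest other gave 3. As many as the real 12 unadjusted calls came from 6 splits, the real one included, with 80 as the highest other, and as many as the real 3 lists from 7 splits, with 9 as the highest other. The splits that joined the libraries numbered 1 gave 32 to 80 unadjusted calls, several times the real count, which points to a structure of the samples. Of the 4 splits that part all 3 pairs, the other 3 gave up to 1 adjusted call, 41 unadjusted calls and 6 lists.

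The 7 members grouped as lymphocyte miRNAs, arms of miR-142a, miR-150, miR-155 and miR-342, were mostly high in both libraries numbered 1. The group name does not exclude other leukocytes as their source. Against the mean of the other controls, control 1 held miR-150-3p higher by 3.91 on the log2 scale, but miR-342-3p by 0.28 and miR-342-5p by 0.16. A lower share of acinar RNA would raise the markers of every other cell alike. Its test was chosen after the values were seen and rests on miR-223-3p. Relative to the other libraries of its group, the median lymphocyte member exceeded miR-223-3p by at least 2.76 on the log2 scale in both groups. In control 1, miR-223-3p itself stood at -1.97 on this scale. Other non-acinar miRNAs were mixed. In control 1 and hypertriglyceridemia 1, miR-143-3p (1.67 and 0.89) and miR-451a (1.06 and 0.98) were higher. In the same libraries, miR-126a-3p (-0.06 and 0.11) changed little, and miR-200b-3p (-0.13 and -0.65) was lower. In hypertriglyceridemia 1, the shallowest library, the size of the steps argues against sequencing depth for the 7 members. Depths were 1.58 times apart from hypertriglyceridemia 3 to 1, and 1.79 times apart from 2 to 3. The log2 step of the members was the larger from 3 to 1 in 7 of 7, by a median of 2.09 (0.14 to 5.24). In levels already scaled to depth, they rose 3.34 to 37.3 times from 3 to 1 (median 7.28). From 2 to 3 the range was 0.99 to 3.74 times (median 1.26). The members were grouped after their values were seen, so this covers these members in 1 library only. In control 1 every member was higher than in control 2 (1.26 to 23.9 times), at nearly equal depth. Depth cannot make that difference, so for control 1 against control 2 the values argue against it. Against control 3, which was deeper, depth was not decided. The median member was 1.499 times as high as in control 2, just short of the limit of 1.5. Whether such a median exceeds ordinary differences between libraries stays open. Its place at percentile 98.2 of 10000 lists matched on mean level decides nothing. The members were grouped after their values were seen, and arms of 1 hairpin vary together. RNA of lymphoid cells or tissue may be the source and stays open, since that 6 of the 7 tested members were highest in the library numbered 1 in both groups restates the pattern; the design names no biological difference between the replicate numbers, so none was tested.

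The pair miR-7a-5p and miR-7b-5p lay higher in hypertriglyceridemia. That the same reads were counted for both is argued against by their counts, which would then be equal: miR-7b-5p had at most 0.194 times the count of miR-7a-5p (0.161 to 0.194 over the 6 libraries). A fixed fraction of miR-7a-5p reads may have been counted for miR-7b-5p and stays open, since the chi-square per degree of freedom of 25.8 for a constant ratio takes amplified reads as independent molecules. A larger islet share may contribute and cannot be told apart: the median of 5 other islet miRNAs was 0.040, and 0.29 without both libraries numbered 1, but none of these is known to be made in islets only. The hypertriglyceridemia itself stays open and untested: miR-7b-5p was called only without control 1 or without both libraries numbered 1, and miR-7a-5p only without both.

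The Dlk1-Dio3 list was called with the preset correlation of 0.01. A candidate explanation is that members of 1 cluster vary together, which makes that p too small. The estimated correlation was 0.33, and with it camera gave an unadjusted p of 0.201 and an adjusted p of 0.733, a value shared with other lists. If that estimate holds, the camera p at the preset correlation is too small. The loss of the call alone does not settle this, since that fit also has fewer degrees of freedom. The stellate and mesenchymal list, with an estimated correlation of 0.0259 near the preset, lost its camera call as well. Its unadjusted camera p went from 0.000901 to 0.0402 (adjusted p = 0.723). Without control 3 the Dlk1-Dio3 call ended at the preset correlation too (adjusted p = 0.0689). Over the 12 alternatives with camera the adjusted p of this list ran from 1.16e-10 to 0.733. A response of the cluster to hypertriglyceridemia stays open and was not tested apart from this.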
